A study of Mus musculus with 13 samples.

How the data were processed

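Adipose tissue of male C57BL/6J mice was profiled on 13 arrays. Fv2E-PERK is a fusion of the kinase domain of PERK, the endoplasmic reticulum stress kinase, with a dimerization domain that the bivalent ligand AP20187 brings together. Per the labels' protocols, AP20187 at 100 ng/g or its vehicle was injected intraperitoneally and tissue was taken 12 h later. That protocol speaks of muscles, whereas every sample is labelled white adipose tissue (WAT) or brown adipose tissue (BAT). Total RNA was labelled with Cy3 and hybridised to 1-colour Agilent arrays. Per the file headers the array design is 028005 on build mm9.

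Per the file headers, the deposited processed signal is an intensity that Feature Extraction 10.7.1.1 had background-subtracted and detrended within each array, with no scaling between arrays. The authors' value table gives intensity as well. It equalled the processed signal, averaged over the spots of a probe, within 0.1% for 99.0 to 99.2% of its values, so no scaling or centring was found in it. Its low cells were blank, by a rule that the labels do not give. On WAT AP20187 1 to 3 the blank share was 18.1%, 14.9% and 32.8%. Column medians, taken over the other cells, therefore do not compare brightness between arrays. Over all spots of those arrays the median processed signal was 22.7, 18.2 and 19.2. The column medians of that table were 97.5 and 83.8 for WAT vehicle 1 and 2, 89.7, 94.2 and 88.1 for wild type 1 to 3, 48.7, 32.8 and 91.6 for WAT AP20187 1 to 3, 52.1 and 57.7 for BAT vehicle 2 and 3, 59.7 and 52.4 for BAT AP20187 1 and 2, and 105 for the array with contradictory labels.

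Of 55681 non-control probes, 26056 matched the RefSeq accession of 1 gene, 0 matched several, and 29625 stayed without a name, for 19752 named genes. Names came from RefSeq records of assembly GRCm38.p6, matched without version numbers. Spots marked as outliers were dropped, which left 948 missing values, and spots of a probe were averaged. The value analysed was log2 of the processed signal minus the 75th percentile of the array. Every level below is on this scale unless a fold is given. Probes entered the test if they were well above background on every array of at least 1 of the 5 groups. This left 32611 probes. For each gene the probe with the highest mean signal was used, which gave 24456 features, 15083 of them named.

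Groups followed the labels: untreated wild-type WAT (3 arrays), Fv2E-PERK WAT with vehicle (2) or AP20187 (3), and Fv2E-PERK BAT with vehicle (2) or AP20187 (2). The 13th array was left out of all groups, because its title and tissue label say BAT and its source name says WAT. The 12 arrays were fitted in 1 model with limma 3.58.1 (lmFit and eBayes) under R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. Of the 30 gene lists, 29 had at least 3 tested members and were tested with camera at a preset inter-gene correlation of 0.01. Camera with an estimated correlation was run beside it. In all, 458 memberships of 487 were tested. List shifts are given as the mean log2 change of the members minus the median change of all features. The labels do not say whether arrays come from separate animals, so p-values measure the spread between arrays. The small number of arrays limits the precision.

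The named genes follow a fixed rule. In each comparison these were the 10 largest rises and falls (6 for the difference between the responses of the tissues, for AP20187 versus wild type and for BAT versus WAT) among genes past the threshold, with groups that did not overlap, a probe above background on every array of the higher group, and an established symbol. Where none passed, the 5 smallest p-values were taken. Up to 4 members of each list, and Eif2ak3, Ucp1 and Lep, were added. Some genes that the rule names are not reported here. The groups, tests, gene lists, naming rule and all alternatives not named below as later choices were set before the data were examined. Where a probe was not well above background on any array of a group, only a bound can be had. "At least N-fold" then sets the mean of the brighter group against the higher, per array, of the probe's own signal and the lowest signal of a probe well above background.

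The arrays lie on 3 slides. Wild type 1 to 3 and WAT vehicle 1 share slide 1, WAT vehicle 2, WAT AP20187 1 to 3 and the array with contradictory labels share slide 2, and all BAT arrays share slide 3. The alternatives were quantile scaling, with and without normexp background correction (offset 50), the authors' value table, no filter or a stricter filter on dim probes, the mean of a gene's probes, only the compared arrays, a trended prior, slide as a fixed or random block, the replicate number as a block, the 13th array in either tissue, and each array left out. Normexp used the median spot signal, since the mean signal is not in the files. Chosen after seeing the data were the percentile over probes detected on all 12 arrays, leaving out weak areas, and leaving out the arrays with epididymal transcripts. A weak area was a block of 12 by 8 spots with at least 10 usable spots (above -1 log2 on the other arrays of the tissue), whose median difference from those arrays was under -0.5 log2, with the blocks next to it.

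The procedure was tested on simulated data with 100 changed features per effect size. Features were drawn independently of each other, and far fewer were changed than were called between the tissues. The shares recovered therefore need not hold for the real comparisons. Of changes of 1 and 2 log2 units it recovered 10% and 52% in WAT AP20187 versus vehicle, 8% and 46% in BAT, 0% and 11% for the difference between tissues, 15% and 66% for vehicle versus wild type, 16% and 58% for AP20187 versus wild type, and 19% and 52% for BAT versus WAT.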

Results

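White and brown adipose tissue of Fv2E-PERK mice, and white adipose tissue of wild-type mice, were measured on 12 arrays in 5 groups. White fat (WAT) came from untreated wild-type mice (3 arrays) and from Fv2E-PERK mice given vehicle (2) or AP20187 (3). Brown fat (BAT) came from Fv2E-PERK mice given vehicle (2) or AP20187 (2). Signal over background differed between groups. The share of spots well above background was 57.9%, 58.9% and 60.6% in wild-type WAT, 61.2% and 64.0% in WAT with vehicle, 51.5%, 49.0% and 51.4% in WAT with AP20187, 46.8% and 49.0% in BAT with vehicle, and 46.4% on both BAT arrays with AP20187. Eif2ak3, the gene of PERK, averaged 1.02 ± 0.14 (SD, n = 3) in wild-type WAT, 1.05 ± 0.16 (n = 2) in WAT with vehicle, 1.25 ± 0.14 (n = 3) in WAT with AP20187, 0.92 ± 0.02 (n = 2) in BAT with vehicle and 1.17 ± 0.01 (n = 2) in BAT with AP20187. Whether its probe lies in the part of the gene that the transgene carries is not known.

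**Figure D1:**
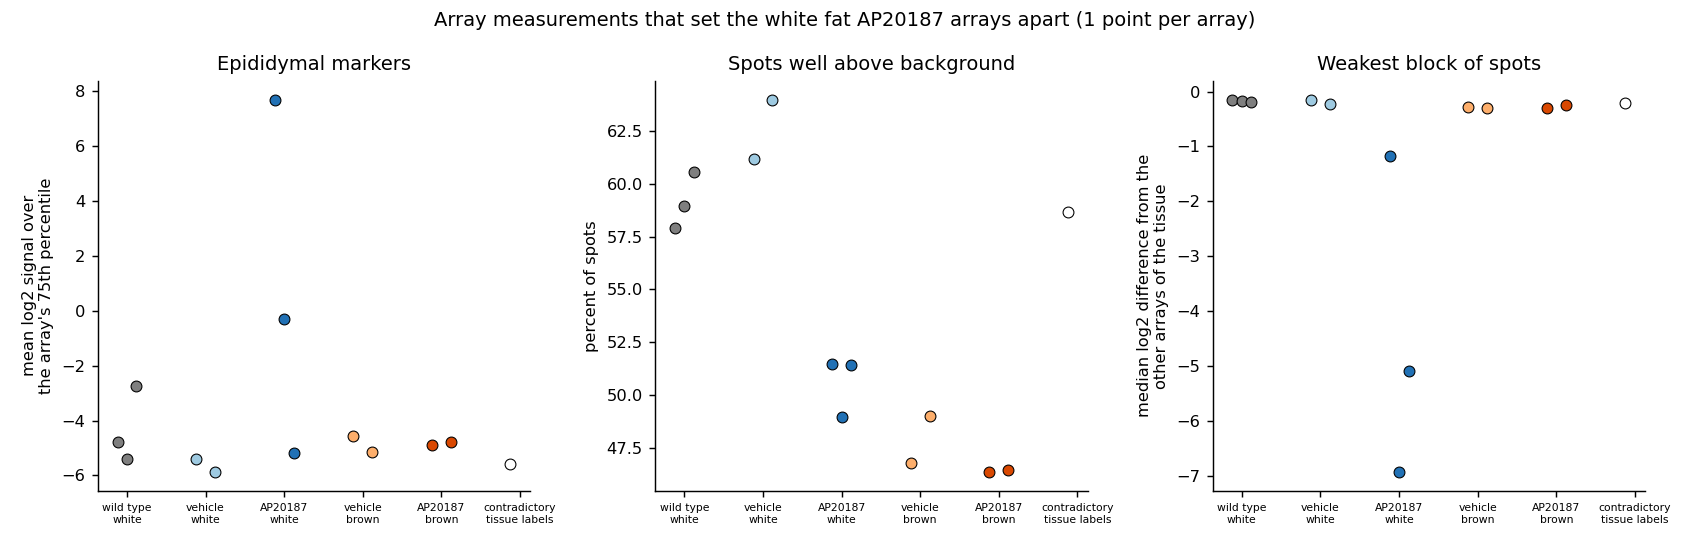
Each point is 1 array, grouped along the horizontal axis, and the panels show the mean log2 signal of epididymal markers, the percent of spots well above background, and the lowest block median of the log2 difference from the other arrays of the tissue. The white fat AP20187 arrays sit at 7.69, -0.30 and -5.20 in the first panel, at 49.0% to 51.5% in the second, and at -1.18, -6.93 and -5.09 in the third, where all other arrays lie at -0.31 or higher.

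The first question was what had changed in white fat of Fv2E-PERK mice 12 h after AP20187. No wild-type group was given AP20187, so effects of the ligand itself and of the activated kinase cannot be told apart. Genes of the cholesterol synthesis list moved up together: 19 of 20 measured members had a positive log2 change, none passed over all genes, and 12 rose when adjusted over the list alone. Among these were Fdps, which makes farnesyl diphosphate (3.13-fold, SE 0.37 log2 units, n = 3 and 2), and Stard4, a sterol carrier (1.83-fold, SE 0.26). The list lay 0.90 log2 above the median of all features (adjusted p = 1.69e-04; adjusted p = 0.81 with an estimated correlation). Interferon-stimulated genes were lower as a group by the same test, at -0.80 log2 (14 genes, adjusted p = 1.15e-04; adjusted p = 0.81 with an estimated correlation), with 0 of them past limma's threshold singly. Without AP20187 array 1 this shift was -0.57 (adjusted p = 0.0026). That array was also the lowest WAT array of the 5 groups for endothelial markers (0.99, the others 2.84 to 3.32), macrophage markers (1.24, the others 1.81 to 2.66) and adipocyte markers (5.95, the others 6.67 to 7.25).

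Genes of 4 further lists were higher as groups in white fat after AP20187. Glycolysis genes lay 0.52 log2 above the median of all features, with 17 of 17 changes positive and 0 past the threshold singly (adjusted p = 0.00128). Among them Pkm, which encodes pyruvate kinase, measured 1.71-fold higher (SE 0.24 log2 units) and Hk2, a hexokinase, 2.09-fold (SE 0.37). The list did not pass with quantile scaling (0.21, adjusted p = 0.12), with normexp as well (0.23, adjusted p = 0.093) or with the contradictory array in BAT vehicle (adjusted p = 0.071). Genes of the respiratory chain and citrate cycle lay 0.30 log2 above (28 genes, adjusted p = 0.00128), with quantile scaling -0.12 and with normexp and quantile scaling -0.06. Without AP20187 array 1 they lay 0.48 above and without array 3 0.16, and they did not pass without a filter on dim probes (0.17, adjusted p = 0.062), with a stricter one (0.19, 0.051) or with the contradictory array in BAT vehicle (0.34). The list of endoplasmic reticulum chaperones, which also holds translocon genes, lay 0.37 log2 above (23 genes, adjusted p = 0.00391). Of its genes 1, Ssr1 of the translocon, rose 1.68-fold (SE 0.14, adjusted p = 0.0459), and 2 passed when adjusted over the list alone. The chaperone list did not pass with quantile scaling (0.16, adjusted p = 0.32), with normexp as well (0.18, 0.31), without a filter (0.24, 0.10), with the stricter one (0.28, 0.080) or without both arrays with epididymal transcripts (0.14, 0.063). It lay 0.09 log2 above the median without AP20187 array 1, with an adjusted p of 0.13, and that array carried transcripts of the epididymis (list mean 7.69, against -5.87 to -2.74 on vehicle and wild-type arrays). Genes of tRNA synthetases, which charge tRNA with amino acids, lay 0.24 log2 above (20 genes, adjusted p = 0.00809), and the adjusted p was 0.12 without vehicle array 2. That list lay 0.12 above without AP20187 array 3, and did not pass with quantile scaling (0.11, adjusted p = 0.055), the authors' value table (0.11, 0.15), no filter (0.11, 0.11) or the stricter filter (0.28, 0.099). With an estimated correlation the adjusted p was 0.81 for glycolysis, chaperones and tRNA synthetases and 0.85 for the respiratory chain.

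Target genes of the integrated stress response, to which PERK belongs, were also measured in white fat. Of its 20 regulators 0 passed, 12 were higher, and the list lay -0.01 log2 from the median (adjusted p = 0.90). Its mean was 2.63, 2.88 and 3.37 on AP20187 arrays 1, 2 and 3 and 2.82 and 2.92 with vehicle. Arrays 1 and 2 carried epididymal transcripts (list means 7.69 and -0.30, against -5.20 on array 3), and only array 3 lay above both vehicle arrays. The shift of the list lay between -0.22 and 0.35 over the settings tried, past the threshold in 0 of them. A response of these regulators in white fat was thus neither shown nor excluded. Atf4, the central transcription factor, measured 1.87-fold (SE 0.39 log2 units, adjusted p = 0.22). Fgf21, a hormone released under such stress, had log2 levels of -0.61, 0.40 and 0.44 after AP20187 and -4.67 and -3.87 with vehicle, a 20.4-fold difference (SE 1.12) that did not pass over all genes (adjusted p = 0.0746) and rose when adjusted over the list of stress hormones alone. In that list 3 of 7 were higher, at a shift of 0.22 (adjusted p = 0.71).

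Among single genes of white fat, Tiam2, an activator of the GTPase Rac, rose 3.62-fold, from -1.65 ± 0.07 (SD, n = 2) to 0.20 ± 0.46 (n = 3), with an adjusted p of 0.0459. Rab3a, a GTPase of vesicle release, rose 2.77-fold, from 2.32 ± 0.25 (n = 2) to 3.79 ± 0.21 (n = 3), and Runx1, a transcription factor, 2.92-fold (SE 0.32 log2 units). The other largest rises lay between 2.60-fold and 3.29-fold: Mro, Parm1, Nme6, Pgp, Mtss1, and Mlx and Paox, each measured on 2 of the AP20187 arrays. From the authors' value table the log2 change was 0.15 for Mlx and 0.60 for Paox. The clock gene Per2 fell 6.76-fold (SE 0.49), from -1.13 ± 0.21 (n = 2) to -3.89 ± 0.63 (n = 3), and was above background on 1 of the 3 AP20187 arrays. Zbtb16, a zinc-finger repressor, fell 7.14-fold (SE 0.52), from 4.74 ± 0.12 to 1.90 ± 0.60. Ces1g, a carboxylesterase, fell 6.19-fold (SE 0.45), with 1 of 3 AP20187 arrays above background, as did Dnaic2 (7.54-fold). Ctxn2, Lao1, Tnni3, Gk2, Hoxa13 and Elf4 were not well above background after AP20187, at least 3.27-fold, 2.48-fold, 2.20-fold, 1.85-fold, 1.76-fold and 1.38-fold below vehicle.

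In all, 548 of 24456 features passed in WAT with AP20187 versus vehicle (limma, adjusted p under 0.05), of which 428 rose and 120 fell; 5449 had an unadjusted p under 0.05. The median of all features lay 0.15 log2 higher after AP20187, and with the percentile taken over probes detected on all arrays it lay at -0.16. On that scaling 7 rose and 220 fell, and 124 of these 227 were among the 548. Quantile scaling gave 0 rises and 2 falls, quantile scaling with normexp 2 and 4, and no call was made from the authors' value table (0 by limma). AP20187 arrays 1, 2 and 3 had areas of weak signal that covered 9.09%, 15.4% and 3.93% of their spots, and without those areas 124 rose and 143 fell. Hoxa13, Mlx, Mro, Paox, Parm1, Pgp, Runx1, Ssr1 and Zbtb16 then no longer passed (adjusted p = 0.051 to 0.061), and Ctxn2, Dnaic2 and Elf4, with a spot in such an area, still did. The count was 0 without wild-type array 1, 2 or 3 or BAT AP20187 array 1 or 2, 2 (both falls) without BAT vehicle array 2 or 3, 5 (all falls) without WAT vehicle array 1, 13 (all falls) without WAT AP20187 array 2, 137 without WAT vehicle array 2 and 2258 without WAT AP20187 array 1; where it was 0, at least 4549 features had an unadjusted p under 0.05. With slide as a block, which sets AP20187 against vehicle array 2 on the same slide, 6 passed (1 rise, 5 falls). The log2 change within that slide was 1.80 for Tiam2, 1.29 for Rab3a, -2.61 for Per2 and -2.92 for Zbtb16. All 6 lists passed with that block, at within-slide shifts of 0.87 for cholesterol synthesis, -0.66 for interferon, 0.54 for glycolysis, 0.30 for the respiratory chain, 0.34 for chaperones and 0.29 for tRNA synthetases. These shifts rest on vehicle array 2 alone, which had the highest liver markers of the white fat arrays (mean 2.83).

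The same question was asked of brown fat. Regulators of the integrated stress response rose as a group after AP20187: 17 of 20 had a positive log2 change, 0 passed over all genes, and 8 rose when adjusted over the list alone. Trib3, a pseudokinase induced by ATF4, measured 6.47 and 8.20 after AP20187 and 3.0 and 2.56 with vehicle (23.5-fold, SE 0.62 log2 units, n = 2 and 2). Chac1, which degrades glutathione, measured 2.27 and 4.03 against 0.24 and -0.75 (10.6-fold, SE 0.60), and Ddit3, the transcription factor CHOP, 3.25 and 4.42 against 2.40 and 2.09 (3.004-fold, SE 0.47). Nupr1, Sesn2, Vldlr, Herpud1 and Jdp2, at 1.98-fold to 2.49-fold, also passed within the list. The list lay 1.003 log2 above the median of all features (adjusted p = 1.37e-07; adjusted p = 0.26 with an estimated correlation).

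**Figure D2:**
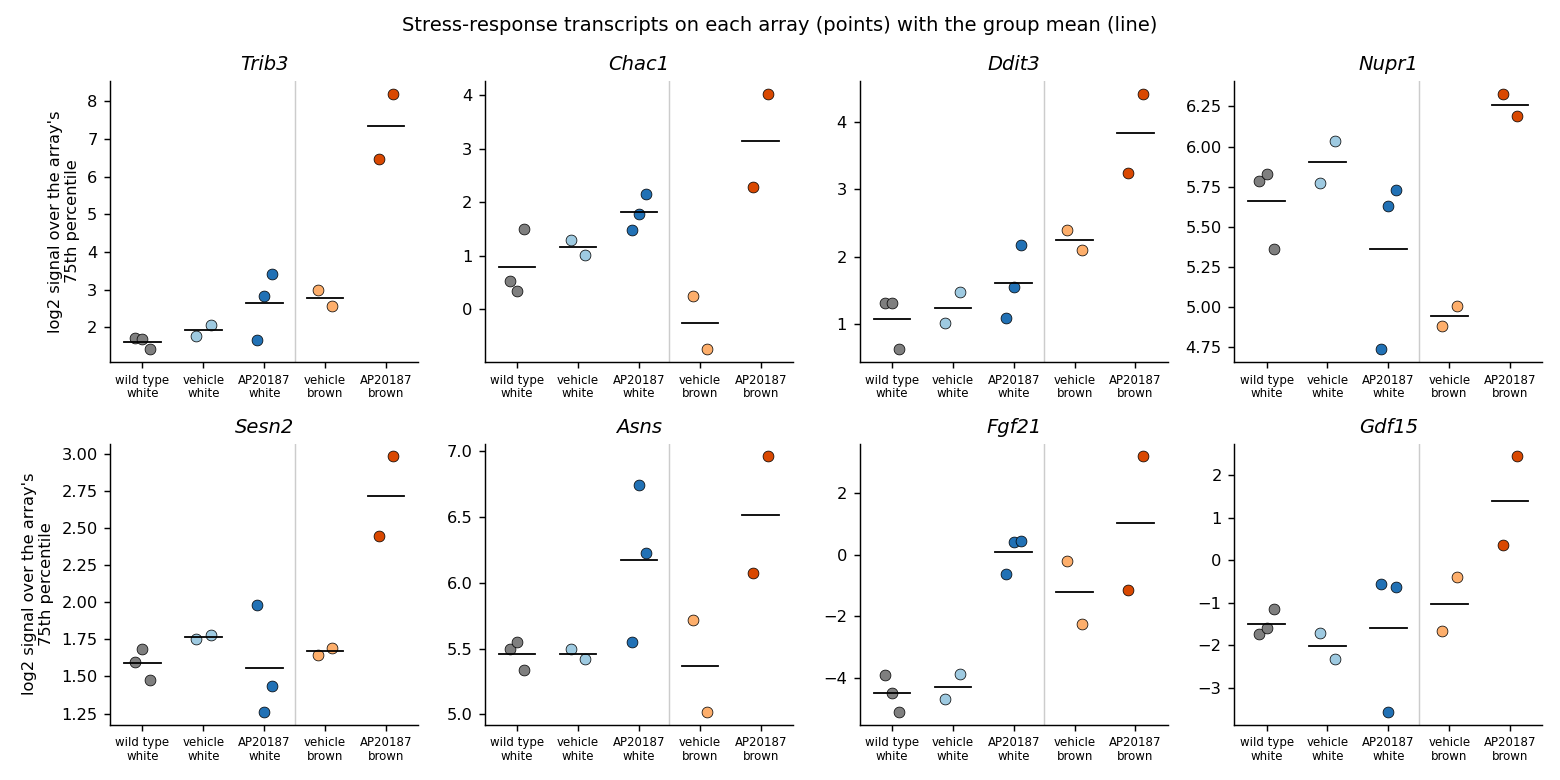
Each point is the log2 signal of a gene on 1 array, relative to the 75th percentile of that array, with a line at the group mean, for 8 genes in the 5 groups and a vertical axis of its own in each panel. In brown fat both AP20187 arrays lie above both vehicle arrays for Trib3 (6.47 and 8.20 against 3.0 and 2.56), Chac1 and Ddit3, whereas Fgf21 overlaps there and is separate in white fat.

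Lists that lie downstream of the same response were also higher on average in brown fat, with larger rises on AP20187 array 2 than on array 1. For each of them array 2 lay above both vehicle arrays. Array 1 lay between the vehicle arrays for amino acid transporters (mean 1.16, vehicle 0.84 and 1.19) and tRNA synthetases (2.654, vehicle 2.662 and 2.43). Genes of amino acid synthesis lay 0.91 log2 above the median (14 of 14 positive, 0 past the threshold, adjusted p = 1.27e-04), with Asns, asparagine synthetase, at 2.21-fold (SE 0.42 log2 units) and Cth of cysteine synthesis at 4.14-fold (SE 0.80). Stress hormones lay 1.13 log2 above (7 genes, adjusted p = 0.00106), and Angptl6 (2.78-fold, SE 0.34) and Sesn2, which is also on the list of regulators, passed when adjusted over the list alone. Amino acid transporters lay 0.72 log2 above (9 genes, adjusted p = 0.0120), and 3 rose when adjusted over the list alone: Slc6a9, a glycine transporter (7.26-fold, SE 0.63), Slc3a2 (2.09-fold) and Slc1a4 (2.01-fold). Genes of tRNA synthetases lay 0.44 log2 above (20 genes, adjusted p = 3.63e-04), with Eprs (2.17-fold, SE 0.25) past the threshold within the list. With an estimated correlation the adjusted p was 0.69 for tRNA synthetases and 0.26 for the other 3 lists.

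Lower as groups in brown fat after AP20187 were cell-cycle genes (-0.88 log2, 19 genes, adjusted p = 2.25e-04), macrophage markers (-0.59, 15 genes, adjusted p = 0.0196), glycolysis (-0.28, 17 genes, adjusted p = 0.0173), matrix and fibroblast genes (-0.26, 17 genes, adjusted p = 0.0439) and cholesterol synthesis (-0.35, 20 genes, adjusted p = 0.0447). Of their members only Ccnb1, a mitotic cyclin, passed when adjusted over the list alone. Its probe was not well above background after AP20187, at least 2.35-fold below vehicle. With an estimated correlation these 5 lists had adjusted p of 0.72 to 0.75. Without BAT vehicle array 3 the shift was 0.05 for cell-cycle genes, 0.21 for macrophage markers (adjusted p = 0.74 and 0.41) and -0.05 for matrix genes (adjusted p = 0.76). That array had the highest mean of skeletal muscle markers, 5.07, against 0.78 on vehicle array 2 and 4.197 and 3.35 on the AP20187 arrays. It was also highest for macrophage markers (1.95, the other brown arrays -0.001 to 0.24) and cell-cycle genes (-0.50, the others -2.55 to -2.14). Lymphocyte markers averaged -1.38 on it, against -2.74 to -2.22 on the others.

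Of single features in brown fat, 2 passed (limma), both as rises, and 1803 had an unadjusted p under 0.05. Snhg12, a host gene of small nucleolar RNAs, rose 4.41-fold, from 1.47 ± 0.01 (SD, n = 2) to 3.61 ± 0.29 (n = 2), with an adjusted p of 0.0456. The other was an unnamed probe, A_55_P2098788, which rose by 2.87 log2 units (SE 0.25, adjusted p = 0.035) and was singled out after its values were seen. The count was 9 (4 rises, 5 falls) without BAT vehicle array 2, 22 (10 rises, 12 falls) without BAT vehicle array 3, 7 without BAT AP20187 array 1, 4 without WAT AP20187 array 1 and 0 without WAT vehicle 1 or 2, any wild-type array or WAT AP20187 array 2 or 3. Where it was 0, at least 1427 features had an unadjusted p under 0.05. Without BAT AP20187 array 2, 6 lists lost their call: amino acid synthesis (shift 0.42, adjusted p = 0.18), amino acid transport (0.20, 0.18), stress hormones (0.53, 0.13), tRNA synthetases (0.17, 0.24), macrophage markers (-0.49, 0.21) and matrix genes (-0.15, 0.44). Without BAT AP20187 array 1 the first 4 lay at 1.40, 1.24, 1.73 and 0.71, and glycolysis lost its call (-0.21, 0.11). Without BAT vehicle array 2, amino acid transport (0.51, 0.090) and glycolysis (-0.12, 0.44) lost theirs, and amino acid synthesis lay at 0.56, macrophage markers at -1.38, cell-cycle genes at -1.84 and matrix genes at -0.49. Cholesterol synthesis turned from falls to rises without BAT vehicle array 2 (0.13, adjusted p = 0.49) or BAT AP20187 array 1 (0.02, 0.99), and lay at -0.71 without BAT AP20187 array 2 and -0.84 without BAT vehicle array 3, where glycolysis lay at -0.47. Cholesterol synthesis and matrix genes also lost it without WAT vehicle array 1 (adjusted p = 0.061 and 0.058) or 2 (0.061 and 0.058), and cholesterol synthesis without WAT AP20187 array 3 (0.051). Both lost it with the stricter filter (0.057 and 0.076), only the compared arrays (0.091 and 0.052), slide as a block (0.061 and 0.058) and the replicate number as a block (0.065 and 0.070), matrix genes with the authors' value table (0.077), and cholesterol synthesis without weak areas (0.059) or both arrays with epididymal transcripts (0.057). Macrophage markers lost it with the value table (0.0502) and the replicate block (-0.34, 0.12). With the contradictory array in BAT vehicle amino acid transport lost it (0.48, 0.10) and glycolysis turned to 0.26 (0.15). All BAT arrays shared 1 slide.

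**Figure D3:**
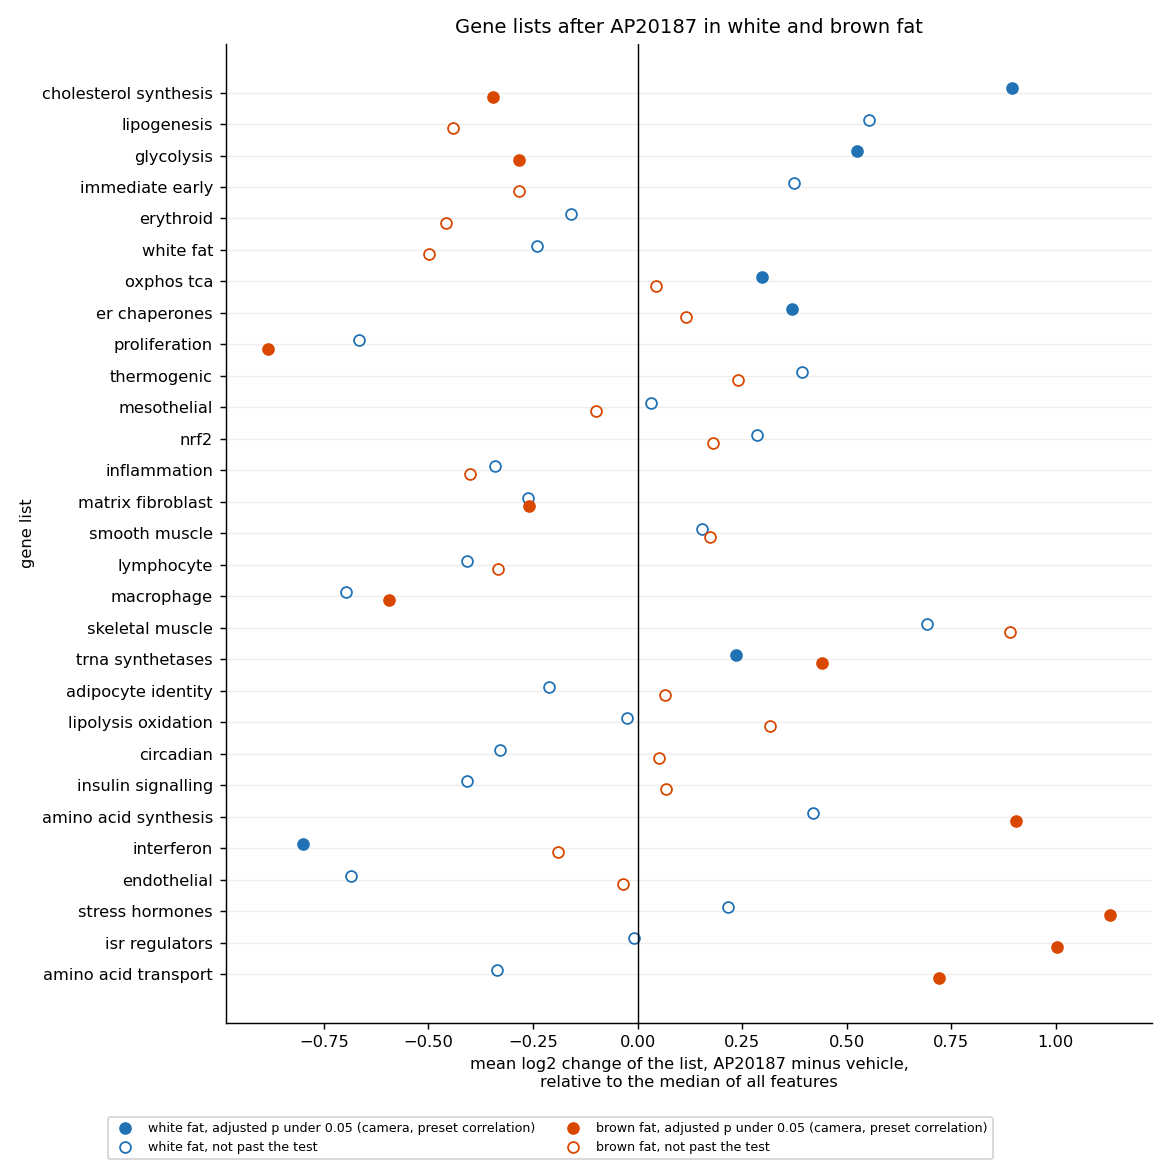
Each point is the mean log2 change of a gene list, AP20187 minus vehicle, relative to the median of all features, in white fat (blue) or brown fat (orange), with filled points past the list test at the preset correlation and lists in order of the difference between tissues. Cholesterol synthesis lies at 0.90 in white and -0.35 in brown fat, and stress response regulators (isr regulators) at -0.01 and 1.003; none of the filled points passed with an estimated correlation, and the respiratory chain (oxphos tca) in white fat lies at -0.12 with quantile scaling and -0.06 with normexp as well.

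Whether the response differed between white and brown fat was tested as the difference of both changes. Cholesterol synthesis responded higher in white fat, by 1.27 log2 relative to the median of all features (adjusted p = 1.16e-04), with 6 of 20 genes past the threshold when adjusted over the list alone. For Fdps the difference was 2.14 log2 units (SE 0.55) and for Stard4 1.61 (SE 0.39). Glycolysis (0.83, adjusted p = 2.07e-04, 4 genes past within the list, among them Pkm at 1.44, SE 0.36), lipogenesis (1.02, adjusted p = 0.0131) and the respiratory chain (0.28, adjusted p = 0.0291) also differed toward white fat. Stress response regulators responded lower in white fat, by -0.98 log2 (adjusted p = 0.00131): Trib3 differed by -3.84 (SE 0.84), Nupr1 by -1.85 (SE 0.44) and Sesn2 by -1.25 (SE 0.36). Of these 20 regulators 5 were lower and 1 higher when adjusted over the list alone. Stress hormones differed by -0.89 (adjusted p = 0.0291), with 1 of 7 lower within the list. With an estimated correlation the adjusted p was 0.74 for cholesterol synthesis, glycolysis, stress regulators and stress hormones and 0.995 for lipogenesis and the respiratory chain.

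No single feature passed for this difference (0 by limma, smallest adjusted p = 0.124, 4033 at an unadjusted p under 0.05). The smallest p-values were those of Rab3a, with a difference of 2.28 log2 units (SE 0.27), Ssh2, a cofilin phosphatase (-3.35, SE 0.43), Snhg12 (-2.18, SE 0.29), the transcription factor Klf15 (-2.67, SE 0.37) and the kinase gene Map3k6 (-2.26, SE 0.30). The count was 398 (312 higher in white fat) without WAT AP20187 array 1, 41 (35 higher) without WAT vehicle array 2, 40 (4 higher) without WAT AP20187 array 3, 3 without BAT vehicle array 3 and 2 without WAT AP20187 array 2 or BAT vehicle array 2. Stress regulators did not pass without BAT AP20187 array 2 (shift -0.66, adjusted p = 0.077) or without both WAT arrays with epididymal transcripts (-0.63, adjusted p = 0.053), nor did stress hormones without it (-0.27, adjusted p = 0.28), BAT vehicle array 2 (0.076) or WAT vehicle array 2 (0.066), from the authors' value table (0.062), with the mean of probes (0.063) or with the percentile over detected probes (0.077). Lipogenesis did not pass without WAT vehicle array 2 (0.089), WAT AP20187 array 3 (0.12), BAT vehicle array 2 (shift 0.46, 0.34) or BAT AP20187 array 1 (0.60, 0.12), nor with quantile scaling (0.63, 0.094), normexp as well (0.66, 0.090), no filter (0.90, 0.064) or the stricter filter (0.95, 0.059). Glycolysis lay at 0.47 with quantile scaling and 0.50 with normexp as well, and passed, but not with the contradictory array in BAT vehicle (0.28, adjusted p = 0.50), with which the respiratory chain lay at -0.54 (0.080). The respiratory chain did not pass without those arrays (0.089, 0.19, 0.34 and 0.050) or without WAT AP20187 array 2 (0.082) or BAT AP20187 array 2 (0.077), and its shift was -0.11 with normexp and quantile scaling and -0.17 with quantile scaling. It also did not pass from the value table (0.18, adjusted p = 0.16), without a filter (0.15, 0.14) or with the stricter one (0.21, 0.12). It lay at 0.45 without WAT AP20187 array 1, 0.15 without WAT AP20187 array 3, and 0.10 and 0.48 without BAT vehicle arrays 2 and 3. Lipogenesis lay at 1.61 without BAT vehicle array 3, cholesterol synthesis at 0.78 without BAT vehicle array 2 and stress hormones at -1.52 without BAT AP20187 array 1. Amino acid synthesis passed without BAT AP20187 array 1 (-0.98, adjusted p = 0.0064) or BAT vehicle array 3 (-0.77, adjusted p = 0.037).

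How white fat of vehicle-injected Fv2E-PERK mice differed from that of untreated wild-type mice, which changes genotype and injection together, was asked next. Interferon-stimulated genes were higher as a group: 14 of 14 had a positive log2 change, 1 passed over all genes, and 11 rose when adjusted over the list alone. Usp18, a negative regulator of interferon signalling, rose 3.45-fold, from -0.58 ± 0.11 (SD, n = 3) to 1.21 ± 0.08 (n = 2), with an adjusted p of 0.0388. Isg15, a ubiquitin-like modifier, measured 3.13-fold (SE 0.28 log2 units), Ifit1 4.40-fold (SE 0.40) and Ifi44 3.14-fold (SE 0.29). The list lay 1.33 log2 above the median of all features (adjusted p = 8.75e-22; adjusted p = 0.15 with an estimated correlation). Chaperones of the endoplasmic reticulum lay 0.33 log2 above, with 23 of 23 positive and 0 past the threshold (adjusted p = 2.56e-04; adjusted p = 0.80 with an estimated correlation). Among them Hspa5, the chaperone BiP, measured 1.79-fold (SE 0.21).

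Lower as groups against wild type were smooth muscle genes (-1.25 log2, 7 genes, adjusted p = 0.00129) and cell-cycle genes (-0.38, 19 genes, adjusted p = 0.0371), both with an adjusted p of 0.99 with an estimated correlation. Without wild-type array 3 the smooth muscle shift was -0.24 (adjusted p = 0.20). That array had skeletal muscle markers at a mean of -1.70, against -3.14 and -3.05 on the other wild-type arrays, and epididymal markers at -2.74, against -4.78 and -5.41. Ces1g, a carboxylesterase, and Vmn2r26, a vomeronasal receptor gene, were not well above background in wild-type fat and rose at least 4.93-fold (adjusted p = 0.0238) and at least 1.21-fold (adjusted p = 0.0388).

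In all, 6 features passed, all as rises (limma), and 1228 had an unadjusted p under 0.05. With the percentile over probes detected on all arrays 7 rose and 1 fell, and with normexp and quantile scaling 2 rose and 1 fell. Within slide 1, where vehicle array 1 lies beside the wild-type arrays, the shift was 1.48 for interferon genes, 0.30 for chaperones, -1.23 for smooth muscle and -0.25 for cell-cycle genes, and the log2 change was 4.46 for Ces1g, 2.48 for Vmn2r26 and 1.84 for Usp18. These equal the values with slide as a block, with which 56 features passed, 13 as rises and 43 as falls, and cell-cycle genes did not (adjusted p = 0.34). The count was 56, again 13 rises and 43 falls, without WAT vehicle array 2, 27 without WAT AP20187 array 1, 3 without BAT AP20187 array 1 or 2, and 0 without wild-type array 3, where 775 features had an unadjusted p under 0.05. Cell-cycle genes also lost their call without WAT vehicle array 1 (adjusted p = 0.081) or 2 (0.34), wild-type array 2 (0.23), or WAT AP20187 array 1 (0.067) or 2 (0.053). They did so with quantile scaling (0.10), no filter (0.12), the stricter filter (0.10), the replicate number as a block (0.17), the percentile over detected probes (0.12), the contradictory array in WAT vehicle (shift -0.15, 0.44) or BAT vehicle (0.052), and without both arrays with epididymal transcripts (0.088). Smooth muscle genes lost theirs with only the compared arrays (0.074).

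White fat after AP20187 was also set against untreated wild-type fat, where genotype, injection and AP20187 change together. The list of endoplasmic reticulum chaperones, translocon genes included, was higher as a group. In it 23 of 23 were positive, 6 passed the threshold over all genes and 16 when adjusted over the list alone. Hspa5 rose 3.05-fold, from 5.89 ± 0.09 (SD, n = 3) to 7.50 ± 0.39 (n = 2), with an adjusted p of 0.0262. Dnajb9, a co-chaperone of BiP, rose 1.79-fold (SE 0.15 log2 units), Sec61b of the translocon 1.86-fold (SE 0.17) and Ssr1 1.84-fold (SE 0.12). The list lay 0.70 log2 above the median of all features (adjusted p = 4.17e-06; adjusted p = 0.76 with an estimated correlation). Its mean was 4.78 on AP20187 array 1, which carried transcripts of the epididymis, 3.83 and 3.99 on arrays 2 and 3, and 3.27 to 3.51 on the wild-type arrays. Without array 1 the list lay 0.41 log2 above and passed. Fgf21 rose 23.6-fold (SE 1.002), from -4.48 ± 0.60 (n = 3) to 0.07 ± 0.59 (n = 3), with an adjusted p of 0.0331. Psph of serine synthesis (3.07-fold, SE 0.34), the transporter gene Slc3a2 (2.29-fold, SE 0.23) and the lipogenic regulator Srebf1 (3.67-fold, SE 0.37) also rose. Of the clock genes Per3 fell by 3.42 log2 units (SE 0.51) and Per2 fell 5.93-fold (SE 0.43), each above background on 1 of 3 AP20187 arrays, Tef fell 2.88-fold (SE 0.29) and Arntl rose 3.07-fold (SE 0.38).

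The largest rises against wild type were in genes best known from liver: Slc27a5, a bile acid ligase (76.6-fold, SE 1.05 log2 units), the cytochromes Cyp2c54 (57.9-fold, SE 1.29), Cyp2a4 (48.6-fold, SE 0.98), Cyp2c50 (38.6-fold, SE 1.04) and Cyp3a16 (37.2-fold, SE 1.15), and Cyp2c39 (at least 10.96-fold, not well above background in wild type). Liver markers, a list chosen after the data were seen, averaged 0.36, -0.06 and 0.13 on the AP20187 arrays, -0.06, -1.31 and -1.93 on the wild-type arrays, and -0.87 and 2.83 on vehicle arrays 1 and 2. Over the 10 largest named rises, Fgf21 among them, vehicle array 2, on the slide of the AP20187 arrays, exceeded vehicle array 1 by a median of 4.58 log2 units. Ctxn2, Plxnb3, Lao1 and Elf4 fell to signals not well above background, by at least 2.70-fold, 3.36-fold, 3.10-fold and 1.89-fold, and Dnaic2 fell 7.85-fold (SE 0.54), with 1 of 3 AP20187 arrays above background.

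Other lists were higher against wild type: cholesterol synthesis (0.78 log2, 20 genes, 2 past over all genes and 10 when adjusted over the list alone, with Hmgcs1 at 2.25-fold and Fdps at 2.81-fold), glycolysis (0.47, 17 genes, 0 and 6), interferon genes (0.54, 14 genes, 3 and 7, with Usp18 at 2.34-fold), lipogenesis (0.67, 22 genes, 2 and 2), the respiratory chain (0.29, 28 genes, 0 and 5) and tRNA synthetases (0.20, 20 genes, 1 and 1). Their adjusted p were 0.00147, 0.00440, 0.00926, 0.0180, 0.00190 and 0.0180. Lower as groups were cell-cycle genes (-1.04, 19 genes, adjusted p = 0.00147), of which Tyms of thymidylate synthesis rose 2.03-fold (adjusted p = 0.0402; log2 change 0.000526 with slide as a block), and smooth muscle genes (-1.09, 7 genes, adjusted p = 0.0252). With an estimated correlation the adjusted p was 0.957 to 0.998 for these 8 lists. The respiratory chain lay at -0.09 with normexp and quantile scaling and at -0.14 with quantile scaling. Also without a call were glycolysis (0.15, adjusted p = 0.26), lipogenesis (0.33, 0.19) and tRNA synthetases (0.05, 0.17) with quantile scaling, and with normexp as well (0.16, 0.33; 0.35, 0.17; 0.12, 0.14). The stricter filter ended the calls of glycolysis (0.32, 0.066), lipogenesis (0.58, 0.12) and tRNA synthetases (0.26, 0.12), no filter those of interferon genes (0.37, 0.062), lipogenesis (0.50, 0.14) and tRNA synthetases (0.04, 0.13), and the authors' value table that of tRNA synthetases (0.08, 0.20). The contradictory array in BAT vehicle ended those of glycolysis (adjusted p = 0.12) and the respiratory chain (0.38). Smooth muscle genes did not pass without wild-type array 3 (-0.09, adjusted p = 0.93) or WAT AP20187 array 1 (0.056) or 3 (0.091), with only the compared arrays (0.058), with the percentile over detected probes (0.18) or without both arrays with epididymal transcripts (0.13). Without WAT AP20187 array 3, glycolysis (0.39, adjusted p = 0.059), interferon genes (0.41, 0.063), lipogenesis (0.44, 0.24), the respiratory chain (0.16, 0.063) and tRNA synthetases (0.09, 0.063) did not pass either, nor did lipogenesis without WAT AP20187 array 2 (0.42, 0.11). Without WAT AP20187 array 1 lipogenesis lay at 1.103 and the respiratory chain at 0.46, and without wild-type array 1 smooth muscle genes at -1.65.

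In all, 2169 features passed against wild type (limma), of which 1762 rose and 407 fell, with 6991 at an unadjusted p under 0.05. The median of all features lay 0.16 log2 higher, and at -0.21 with the percentile over probes detected on all arrays, where 104 rose and 1023 fell. Rises and falls were 65 and 39 with quantile scaling, 145 and 71 with normexp as well, and 900 and 374 in the authors' value table. With weak areas left out 1184 rose and 595 fell; Ctxn2, Dnaic2, Elf4, Plxnb3, Slc27a5, Cyp2a4, Hspa5, Hmgcs1, Tef and Usp18 have a spot in a weak area of at least 1 AP20187 array. The count was 0 without wild-type array 1, 2 or 3, where at least 4932 features had an unadjusted p under 0.05, 56 (10 rises, 46 falls) without WAT AP20187 array 2, 1229 without WAT AP20187 array 3, 1418 without either WAT vehicle array and 5342 without WAT AP20187 array 1. No slide holds both groups. With slide as a block, estimated through the vehicle arrays of both slides, 0 features passed, and the list shifts were 0.66 for chaperones, 0.74 for cholesterol synthesis, 0.54 for glycolysis, 0.83 for interferon genes, 0.91 for lipogenesis, 0.33 for the respiratory chain, 0.34 for tRNA synthetases, -0.77 for cell-cycle genes and -1.04 for smooth muscle. The last 2 did not pass with that block (adjusted p = 0.060 and 0.13).

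Vehicle-treated brown and white fat were compared to describe the tissues. Of 20 thermogenic genes 17 rose in brown fat, among them Ucp1, the uncoupling protein, from -6.25 ± 1.38 (SD, n = 2) to 10.26 ± 0.53 (n = 2), not well above background in white fat, Fabp3, a fatty acid carrier (log2 change 10.85, SE 0.62), and Cox7a1 of the respiratory chain (128-fold, SE 0.43). Of 28 genes of the respiratory chain and citrate cycle 26 rose, such as Ndufv1 (8.17-fold, SE 0.24) and Ogdh (7.89-fold, SE 0.22; log2 change 0.45 with the stricter filter, adjusted p = 0.25), as did 12 of 17 glycolysis genes and 14 of 21 genes of lipolysis and fatty acid oxidation, with Cpt1b of fatty acid import at 328-fold (SE 0.45); 2 of the latter fell, Cpt1a by 4.90-fold. Of 15 white fat markers 12 fell, among them Hoxc9 (at least 47.4-fold) and Slc7a10 (28.9-fold, SE 0.30), and the adipokine gene Lep fell by 3.41 log2 units (SE 0.63). All 9 mesothelial markers fell, with Msln at least 186-fold and Wt1 at least 62.1-fold lower and neither well above background in brown fat.

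Of 16 skeletal muscle markers 12 rose in brown fat, such as Tnni2 (143-fold, SE 1.24 log2 units; log2 change 4.97 without BAT vehicle array 3), with list means of 0.78 and 5.07 on the brown arrays and -3.21 and -2.90 on the white ones. Alb and Ahsg, made by liver, were not well above background in brown fat. On WAT vehicle arrays 1 and 2 Alb measured 1.91 and 5.82 and Ahsg 0.27 and 4.98, and array 2 had the highest liver markers. Without array 2 Ahsg passed (adjusted p = 0.0122) and Alb did not (0.14). Among matrix and fibroblast genes 12 of 17 fell and among macrophage markers 6 of 15, with Col1a1 at 2.44-fold (SE 0.21) and Mrc1 at 5.39-fold (SE 0.45), and 7 of 14 immediate early genes rose, with Nr4a1 at 7.03-fold (SE 0.46). In amino acid synthesis 5 of 14 fell and 2 rose, with Phgdh of serine synthesis 16.0-fold lower (SE 0.57), and 4 of 23 chaperones and 2 of 14 interferon genes fell.

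In all, 5732 features differed between the tissues (limma), 3491 higher and 2241 lower in brown fat, and 14 lists passed. The median of all features lay 0.11 log2 higher in brown fat, and at -0.13 with the percentile over probes detected on all arrays, where 2682 were higher and 3392 lower. Mesothelial, thermogenic and white fat markers also passed with an estimated correlation (adjusted p = 0.00424, 0.0150 and 0.0395), and for the other 11 lists the adjusted p was 0.092 to 0.75. Fabp4, a fatty acid carrier of adipocytes, rose 2.37-fold and Scd1, a desaturase, 2.41-fold. Quantile scaling gave Fabp4 a log2 change of -0.19. With normexp as well Scd1 lay at -0.00248 and Fabp4 at -0.32, where Fabp4 passed as a fall (limma, adjusted p = 0.041). The count was 3094 without WAT vehicle array 1, 3287 without WAT vehicle array 2 and 2974 without BAT vehicle array 2. Without BAT vehicle array 2 the calls of macrophage markers (shift -0.94, adjusted p = 0.053), interferon genes (-0.41, 0.16), amino acid synthesis (-1.09, 0.12) and cell-cycle genes (-0.08, 0.88) were lost. Without BAT vehicle array 3 cell-cycle genes lay at -1.98 and skeletal muscle markers at 3.69. Without WAT vehicle array 1 interferon genes (0.15), amino acid synthesis (0.11) and cell-cycle genes (0.082) lost theirs, and amino acid synthesis did so without wild-type array 2 (0.051) or 3 (0.062) or WAT AP20187 array 1 or 2 (0.052 each). Amino acid synthesis also did so with quantile scaling (0.062), the mean of probes (0.058), only the compared arrays (0.066), the percentile over detected probes (0.10), and without weak areas (0.055) or both arrays with epididymal transcripts (0.063). Cell-cycle genes lost theirs with the stricter filter (0.067) and the percentile over detected probes (0.054), and immediate early genes without a filter (0.13). The contradictory array in WAT vehicle ended the calls of interferon genes (-0.45, 0.088) and amino acid synthesis (0.053), and in BAT vehicle those of amino acid synthesis (-0.97, 0.072) and cell-cycle genes (-0.45, 0.21). All BAT arrays lie on a slide without WAT arrays, so for most genes tissue and slide cannot be told apart. The identity markers differed by more than slides 1 and 2 did for the same tissue: on WAT vehicle arrays 1 and 2 and the 2 BAT vehicle arrays, thermogenic markers averaged -0.91, -0.21, 4.95 and 4.47, mesothelial markers 2.07, 1.67, -4.61 and -4.93, and white fat markers 2.27, 2.43, -1.81 and -1.11. A slide difference of the size between slides 1 and 2 is too small for these 3 lists. The effect of slide 3 was not measured and can be larger. Its brightest spike-in control had a signal of 104029 to 121471, against 2598 to 10318 on slides 1 and 2.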

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

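The tests on epididymal transcripts, on detection and the direction of calls against vehicle, and on the 10 largest named rises were chosen after the results were seen; those on all rises against wild type were not, except their repeat with the percentile over detected probes.

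The response to AP20187 differed between white and brown fat for 6 gene lists, by camera on the difference of both changes. The adjusted p was 0.000116 for cholesterol synthesis, 0.000207 for glycolysis, 0.00131 for regulators of the integrated stress response, 0.0131 for lipogenesis, and 0.0291 for both the respiratory chain and stress hormones. With an estimated correlation none of the 6 passed (adjusted p of 0.737 to 0.995).

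The array with contradictory tissue labels, used in no comparison, carried the signal of white fat markers, at a mean of 2.35 log2. White fat arrays lay between 1.15 and 2.65 and brown fat arrays between -2.06 and -1.11. Its thermogenic markers averaged -0.41 (white fat -0.91 to 0.35, brown fat 4.47 to 5.02), Ucp1 measured -4.57 (brown fat 9.87 or higher), and Lep 4.00.

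Epididymal transcripts stood out on 2 of the 3 white fat AP20187 arrays, with list means of 7.69 on array 1, -0.30 on array 2 and -5.20 on array 3, against -5.87 to -2.74 on vehicle and wild-type arrays. Carry-over of epididymal tissue would bring all abundant markers together, and on array 1 87.5% of the measured markers lay over 2 log2 units above every vehicle or wild-type array, so carry-over is a candidate explanation. The highest of the wild-type arrays, array 3, had Crisp1 at 6.68 without AP20187. A response of white fat to AP20187 needs all 3 AP20187 arrays to rise, and only 2 did, but a response that varies between animals was not excluded. Carry-over and such a response therefore cannot be told apart with 3 arrays.

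Fewer spots were above background on the white fat AP20187 arrays (49.0% to 51.5%), while 428 of 548 calls against vehicle were rises. For detection, the vehicle arrays on the same slide argue against a difference between slides. They had 64.0% (vehicle array 2) and 58.7% (that with contradictory labels). The direction of the calls was not covered by this, since vehicle array 1 lies on another slide. The direction depended on the scaling: with the percentile over probes detected on all arrays 3.08% of the calls were rises. That percentile moves all features of an array by the same amount, so the turn does not show which scaling is right. Without both arrays with epididymal transcripts 58 of 537 calls were rises, but without array 1 alone, which carried most of them, 1871 of 2258 were, and without array 2 alone 0 of 13. Weak areas, which lay on the AP20187 arrays alone, were a further candidate, but outside them the lowest share of these arrays was still 50.5%, and they held 23.6% of the called rises and 32.5% of the called falls against 26.9% of all features. In their favour, without those areas rises were 46.4% of the calls (124 of 267), and the median change of all features was 0.08 log2 instead of 0.15. Scaling, weak areas as part of the cause, and a difference between slides for the direction of the calls remain open. So do untested explanations such as RNA quality or a real shift of the transcriptome, and all of these cannot be told apart here.

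In white fat after AP20187 against wild type 1762 of 2169 calls were rises, with a median change of 0.79 log2. Over the rises as a set vehicle array 2 exceeded vehicle array 1 by a median of 0.14, so the slides differed little in that pair. With 1 vehicle array on each slide this does not exclude a difference between slides. The AP20187 mean exceeded vehicle array 2, on its own slide, by 0.66, as a contribution of AP20187 would need. That value is raised by selection, because these features were called as high on the same AP20187 arrays. With the percentile over detected probes the same features had a median change of 0.42, of which 0.06 lay between the vehicle arrays and 0.40 between AP20187 and vehicle array 2. On that scaling 104 features passed as rises and 1023 as falls, and the median of all features lay at -0.21, so the excess of rises depends on the scaling. The 10 largest named rises behaved otherwise. There vehicle array 2 exceeded vehicle array 1 by a median of 4.58 of a change of 5.24. The AP20187 mean exceeded vehicle array 2 by 0.39, less than AP20187 as their cause would need. These values go with a difference between slides. However, the largest rises were in genes best known from liver, and vehicle array 2 had high liver markers (mean 2.83, vehicle array 1 -0.87). Liver transcripts on that array would raise the first value and lower the second, so AP20187 was not excluded. The array with contradictory labels, on slide 2 with liver markers at 0.96, exceeded vehicle array 1 by a median of 4.005. Fgf21 among the 10 went the other way, with 0.80 between the vehicle arrays and 3.95 between AP20187 and vehicle array 2. Of the 10 splits of these 6 arrays 1, the real one, gave as many as 2169 calls and the highest other split gave 0, and 10 splits are too few for a share under 0.05.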

How the results depend on the processing

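The percentile over detected probes, leaving out weak areas and leaving out both arrays with epididymal transcripts were chosen after seeing the data; the other alternatives were not.

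Calls of named genes depended on the comparison. Between the tissues 81 of 82 passed in the same direction under 50% or more of the settings, against 27 of 34 for AP20187 versus wild type, 1 of 3 for vehicle versus wild type, 0 of 1 in BAT and 0 of 21 in WAT with AP20187 versus vehicle, where the 548 calls fell to 0 under several settings. Of all 141 such calls 140 held with an intensity trend, 129 without weak areas, 84 with quantile scaling, 65 with only the compared arrays and 0 with the contradictory array in BAT. The white fat markers of that array lay at 2.35 log2, within the white fat arrays (1.15 to 2.65), so that last setting mixed the tissues. Of the 49 list calls 3 passed with an estimated correlation, 49 with an intensity trend, 47 without weak areas and 37 with quantile scaling. Signal over background limits the bounds given for genes not well above background, and 10% of simulated changes of 1 log2 unit were recovered in white fat. Where leaving out an array left a group with 1 array, that lone array is assumed to vary like the other groups.

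Counts of calls that moved by over 1.5 times are given next; except where the number of tested features or arrays changed, the cause was not tested. Quantile scaling with normexp gave 6 calls in WAT with AP20187 versus vehicle, 1 in BAT, 1 for the difference between tissues, 3 for vehicle versus wild type and 216 for AP20187 versus wild type, and quantile scaling alone 2, 4, 2, 2 and 104. The value table of the authors gave 0 in WAT, 0 in BAT, 0 for vehicle and 1274 for AP20187 versus wild type. Without a filter on dim probes 5512, 0, 12 and 7031 passed in that order, and 11152 between the tissues. A stricter filter gave 1231 in WAT and 1 for vehicle versus wild type, and the mean of probes 315 in WAT. With only the compared arrays 0 passed in WAT, in BAT and for AP20187 versus wild type. An intensity trend gave 1180 in WAT and 187 for the difference between tissues. Slide as a fixed block gave 6 in WAT, 0 in BAT, 56 for vehicle and 0 for AP20187 versus wild type. It could not be fitted for the tissues. As a random block slide gave 1384, 1, 10 and 13480, with an estimated correlation within slides of -0.248. Every group but WAT vehicle lies on 1 slide, so this estimate tells nothing for or against a slide effect, and its counts lend no support. The contradictory array gave 0, 0, 2 and 0 in BAT vehicle, with 0 between the tissues, and in WAT vehicle 1908, 4, 0 and 3280, with 2 for the difference between tissues. The percentile over detected probes gave 227 in WAT, 1 in BAT, 13 for the difference between tissues and 1127 for AP20187 versus wild type. Without weak areas 267 passed in WAT (212 of them among the 548) and 15 for the difference. Without both arrays with epididymal transcripts 537 passed in WAT (58 rises, 479 falls), of which 57 were among the 548, 0 in BAT, 423 for the difference (101 higher in WAT, 322 lower), 20 for vehicle and 1132 for AP20187 versus wild type (276 rises, 856 falls). Where a count was 0, limma gave 775 to 7774 features at an unadjusted p under 0.05.

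With 1 array left out, counts ranged from 0 to 2258 in WAT, 0 to 22 in BAT, 0 to 398 for the difference between tissues, 0 to 56 for vehicle versus wild type, 0 to 5342 for AP20187 versus wild type and 2974 to 8042 between the tissues.

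With the replicate number as a block, 0 features passed in WAT, 0 in BAT, 0 for AP20187 versus wild type and 2 for vehicle versus wild type. The labels do not say whether equal numbers pair the arrays. Deviations of same-numbered arrays from their group means correlated at -0.22 to 0.11. This cannot decide it, since in a group of 2 arrays the deviations mirror each other.

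Values that changed sign follow, and their cause was not tested. The contradictory array had white fat markers at 2.35 log2 (brown fat arrays -2.06 to -1.11), so placing it in BAT vehicle mixed the tissues. The respiratory chain lay at -0.0636 in WAT, -0.11 for the difference between tissues and -0.0889 for AP20187 versus wild type with normexp and quantile scaling, at -0.12, -0.17 and -0.14 with quantile scaling, and at -0.54 for the difference with the contradictory array in BAT, with which glycolysis in BAT lay at 0.26. Between the tissues Fabp4 lay at -0.32 and Scd1 at -0.00248 with normexp and quantile scaling, and Fabp4 at -0.19 with quantile scaling. At -0.32 Fabp4 passed as a fall (limma, adjusted p = 0.041), against a rise in the main fit. With 1 array left out, list shifts in BAT ranged from -0.84 to 0.13 for cholesterol synthesis, -1.38 to 0.21 for macrophage markers and -1.84 to 0.0458 for cell-cycle genes.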

Other observations

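The liver list was chosen after its values were seen, and the list of glucocorticoid targets after the falls of Per2 and Zbtb16 were seen but before its own values were.

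Clock genes and glucocorticoid targets were examined further in white fat. Per2 fell 6.76-fold after AP20187, and Per3 (5.51-fold lower, SE 0.57 log2 units, adjusted p = 0.0583) and Bhlhe40 (2.99-fold higher, SE 0.42, adjusted p = 0.0808) did not pass over all genes. When adjusted over the list of 16 clock genes alone, 2 were lower and 1 was higher, while the list as a whole lay -0.33 log2 from the median of all features (adjusted p = 0.35). Lower glucocorticoid signalling may underlie the lower Per2 and Zbtb16, both known targets of that hormone, and it was tested on other targets: their mean change was -0.32 log2 relative to all features. Of 21 measured targets 10 had a positive change, with a camera p of 0.0519 (0.386 with an estimated correlation), and in brown fat the mean was 0.37 (p of 0.0497, and 0.382 with an estimated correlation). The test leaves the hypothesis open.

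Liver transcripts varied between white fat arrays. Their mean was 2.83 on vehicle array 2, 0.96 on the array with contradictory labels, 0.36 or lower on all other white fat arrays, and between -3.44 and -3.01 on brown fat arrays. Skeletal muscle markers averaged -1.004 on white fat AP20187 array 2, -1.70 on wild-type array 3 and -2.49 or lower on the other white fat arrays.

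WAT AP20187 array 1 correlated with the other white fat arrays at a Pearson r across probes of 0.88 to 0.91, and the other white fat pairs at 0.93 to 0.99; probes are not independent replicates.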
